A study of Mus musculus with 6 samples.

How the data were processed

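Total RNA of 6 samples of BCR-ABL1-transformed mouse pre-B cells with floxed Sox4 was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The labels put 3 samples in the ERT2 group and 3 in the Cre-ERT2 group by the transduced construct, and give mice of 5 weeks and a time of 24 h after 4OHT.

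The deposited table holds 1 intensity per probe set and array. The authors' values came from RMA, which corrects background, normalizes arrays by quantiles and combines the probes of a probe set, per the submitters' processing notes. The software version, annotation and genome build are not given in the sources used here. RMA yields log2 values, whereas the deposited intensities are on a linear scale, as their range of 6.27 to 26714 shows, so log2(intensity + 1) was used throughout. A fold change on this scale understates the change of dim probe sets slightly. Quantile normalization gives every array nearly the same distribution, so a shift of all genes in one direction would not be seen.

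All 35556 probe sets were tested. The probe table names 1 gene for 21789 of them, several for 1621 and none for 12146. Of the first kind 21698 matched a gene identifier of the gene table (assembly GRCm38.p6), and 0 symbols changed. No gene was named from a probe set with several genes. Control probe sets were to be left out, but the sources used here do not mark them, so they were kept, and a test of the named probe sets alone was added after seeing the data. No coordinates are printed, since the build of the array annotation is unknown. A gene was represented by its probe set with the highest mean over the 6 arrays. Of 999 genes with several probe sets 111 had any called, 44 had all called in one direction and 0 were called in opposite directions.

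The comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, no covariates, all 6 samples), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Errors of log2 differences are limma's moderated standard errors, and adjusted p-values of single genes are limma's. For Sox4 an exact two-sided permutation test of 3 against 3 values was added, which cannot give less than 0.1.

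Before the data were examined, 31 gene lists, the design, the alternatives and a rule for the genes named were fixed. The rule took the 15 largest rises and the 15 largest falls among genes past the threshold whose groups did not overlap, Sox4, and up to 4 members of each list with the smallest p. Other genes named were chosen after their values were seen. The lists covered p53 targets, pro-death and pro-survival Bcl-2 relatives, PI3K-AKT, ERK-MAPK, STAT5, Src-family kinases, pre-B cell receptor signalling, early B-lineage factors, V(D)J recombination, later B-cell, progenitor and plasma-cell genes, the Sox family, G2-M, DNA replication, Myc targets, interferon, NF-kB, ATF4 and unfolded protein response, glycolysis and hypoxia, cholesterol synthesis, Wnt, TGF-beta, histones, culture stress, and T-cell, NK-cell, myeloid, erythroid and stromal markers. Lists were tested with camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, and beside it with an estimated correlation and with fry. Matching of list members through older symbols in the gene table was added after first list results had been seen; it let the histone list be tested, and the same 7 lists were called before and after.

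The calling of probe sets and lists was tried on simulated data for the comparison of Cre-ERT2 with ERT2, with 200 of 35556 probe sets changed. It recovered 0% of changes of 0.25 on the log2 scale, 64% of 0.5, 92% of 1 and 100% of 2, with 3.76% false calls. It called 0 lists that had not been shifted. The real data gave 2152 called probe sets, which puts the threshold at a larger unadjusted p, so these shares do not carry over. Simulated probe sets varied independently of each other, so the simulation cannot check list calls where genes vary together.

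Alternatives were an intensity trend or robust fitting in eBayes, the brighter part of the probe sets, median centring, a further quantile normalization, cyclic loess, estimated array weights, the replicate number as a block, a pseudocount of 16, no pseudocount (added after seeing the data), the mean of a gene's probe sets, a minimum fold of 1.5, and each array left out in turn.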

Results

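Gene expression was measured in mouse pre-B cells transformed with BCR-ABL1, the fusion tyrosine kinase of Philadelphia chromosome-positive acute lymphoblastic leukaemia. The cells carried floxed alleles of Sox4, a transcription factor of the SoxC group that is active in B-cell progenitors. In 3 samples the cells had been transduced with ERT2, the hormone-binding part of the oestrogen receptor, and in 3 samples with Cre-ERT2, a Cre recombinase that 4OHT (4-hydroxytamoxifen) switches on. Total RNA was taken 24 h after 4OHT and hybridised to 1 Affymetrix array per sample. Median intensity per array lay between 273 and 279, and the number of arrays limits the precision. Across probe sets, which are not independent replicates, log2 values of arrays of one group correlated with r from 0.995 to 0.997, and those of different groups with r from 0.990 to 0.992. The first principal component held 51.4% of the variance and separated the groups. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

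The study asked what Sox4 does in these leukaemia cells, and the comparison of Cre-ERT2 with ERT2 cells addresses what differs 24 h after deletion was induced. Sox4 itself fell in the Cre-ERT2 cells. Its probe set (10408450) gave a mean intensity of 1356 ± 112 (SD, n = 3) in the ERT2 controls and 546 ± 50.4 (SD, n = 3) in the Cre-ERT2 samples, which is 40.3% of the control mean. The control arrays read 1459, 1372 and 1237, and the Cre-ERT2 arrays read 599, 541 and 499. On the log2 scale the difference was -1.31 (SE 0.091, limma adjusted p = 0.000434), and all 3 Cre-ERT2 samples lay below all 3 controls. The exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest it allows. Where its probes lie relative to the deleted part is not given in the sources used here. None of the 6 samples combines Cre-ERT2 with unfloxed Sox4, and none is labelled as free of 4OHT, so loss of Sox4 and Cre activity cannot be separated in any of the comparisons.

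**Figure D1:**
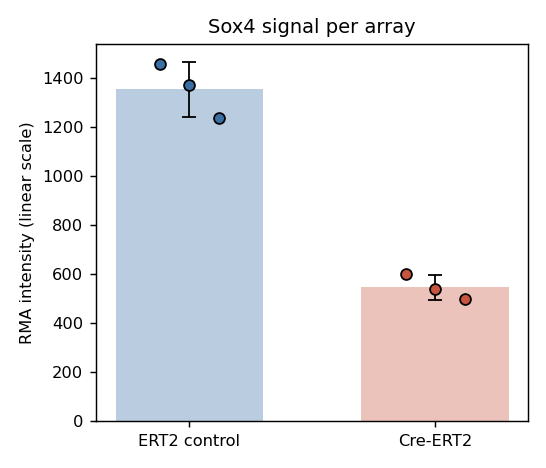
Intensity of the Sox4 probe set (vertical axis, RMA intensity on a linear scale) in the 3 ERT2 control and 3 Cre-ERT2 samples, with points for arrays and bars for group means with SD. The Cre-ERT2 arrays lie between 499 and 599, all below the control arrays at 1237 to 1459.

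Scd1 and Enpep showed the steepest falls. Scd1, the desaturase that makes monounsaturated fatty acids (probe set 10467979), fell by 5.05 on the log2 scale (SE 0.0725), from a mean of 13.25 ± 0.020 (SD, n = 3) to 8.20 ± 0.13 (SD, n = 3). Enpep, the glutamyl aminopeptidase known as the BP-1 antigen of pre-B cells (probe set 10502081), fell by 4.84 (SE 0.126). Stag3, a cohesin subunit of meiosis, fell by 3.69, Casd1, a sialic acid O-acetyltransferase, fell by 3.34, and B3gnt5, which starts lacto-series glycolipids, fell by 3.33. Trim35, an E3 ubiquitin ligase, fell by 3.05, Ncs1, a neuronal calcium sensor, fell by 3.00, and Usp11, a deubiquitinase, fell by 2.88. Edaradd, an adaptor of the ectodysplasin receptor, fell by 2.73. The remaining members of the 15 steepest falls were 1700048O20Rik, Stox2, Prr13, Tceal9 and the neighbouring olfactory receptor genes Olfr372 and Olfr373, which had differences from -3.27 to -2.55. Stox2 had a second probe set with a difference of -0.90. Limma adjusted p-values of these 15 genes lay between 4.93e-06 and 0.000104.

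Pcp4 and Cyyr1 showed the steepest rises. Pcp4, a calmodulin-binding peptide (probe set 10437205), rose by 3.75 on the log2 scale (SE 0.0595), from 9.07 ± 0.079 (SD, n = 3) to 12.82 ± 0.051 (SD, n = 3). Cyyr1 (probe set 10440513) rose by 3.33 (SE 0.0782) and Lrrc4c, a netrin-G ligand, by 2.83. Genes known from lymphocytes among the rises were Gimap4, a GTPase of the immunity-associated family (2.62), Fcrl6, an Fc receptor-like protein (2.47), Jchain, which joins IgM and IgA polymers (2.15), and Ctla4, an inhibitory receptor of T cells (1.83). Fstl1 and Mmp13, a secreted glycoprotein and a collagenase, rose by 2.43 and 2.41. Elovl7, a fatty acid elongase, rose by 2.18, and Egln3, an oxygen-sensing prolyl hydroxylase, by 2.10. The list was completed by the zinc-finger gene Zfp182, the inflammasome sensor Nlrp1a and the glycosyltransferases Galnt14 and St6galnac5, which rose by between 1.93 and 2.08. Limma adjusted p-values of these 15 genes lay between 4.93e-06 and 0.000327.

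Across the array 1143 probe sets were higher and 1009 lower in Cre-ERT2 cells at adjusted p under 0.05, together 6.05% of 35556. Of these, 144 rose and 218 fell by more than 2-fold, and 12 rose and 55 fell by more than 4-fold. In genes, each taken from 1 probe set, 873 were higher and 742 lower. A larger fall than that of Sox4 was seen in 136 probe sets. In 8287 probe sets (23.3%) the groups did not overlap, where chance gives 10%, and 0 of the called probe sets had overlapping groups. The number of higher probe sets was 651 without ERT2 replicate 1, 1319 without ERT2 replicate 2 and 753 without ERT2 replicate 3. It was 697 without Cre-ERT2 replicate 1, 606 without Cre-ERT2 replicate 2 and 607 without Cre-ERT2 replicate 3. The number of lower ones lay between 654 (without Cre-ERT2 replicate 3) and 883 (without ERT2 replicate 3). ERT2 replicate 2 stood farthest from its group: its log2 differences from the other controls had SDs of 0.231 and 0.242, against 0.184 between those.

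**Figure D2:**
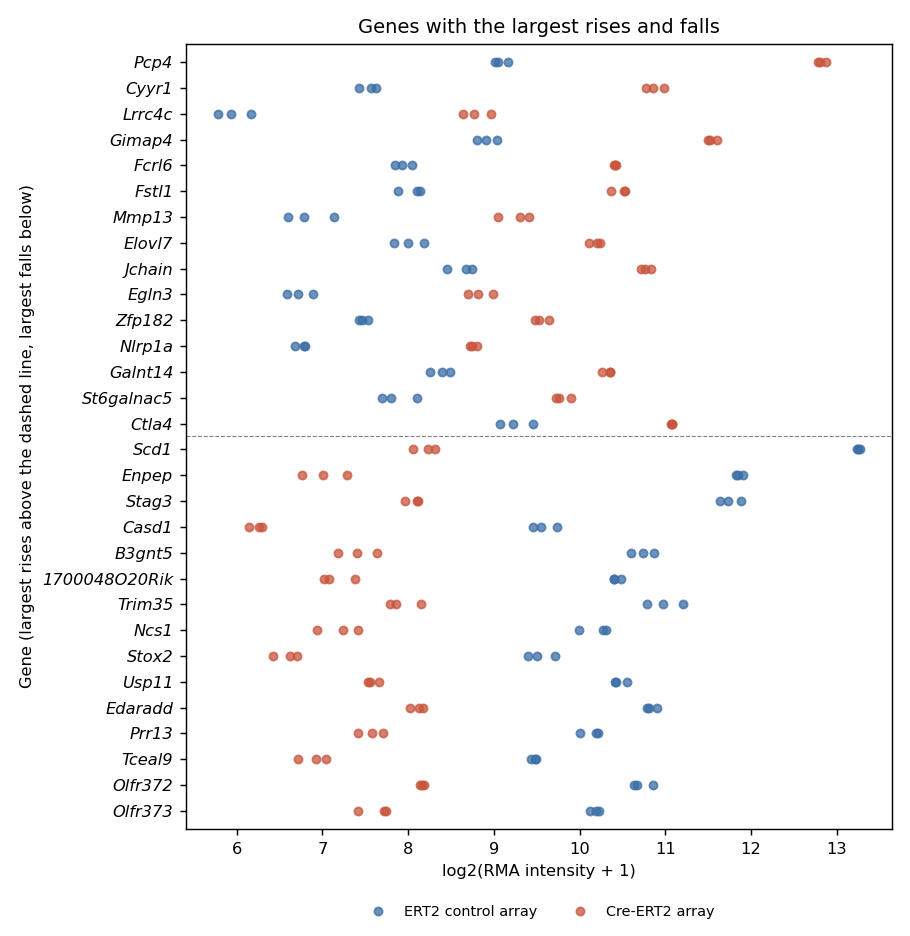
Log2 of the intensity plus 1 (horizontal axis) of the 15 genes with the largest rises and the 15 with the largest falls, 1 row per gene and 1 point per array, for the ERT2 control and Cre-ERT2 samples. In each row the 3 arrays of one group lie apart from the 3 of the other, with the Scd1 means at 13.25 and 8.20 and the Pcp4 means at 9.07 and 12.82.

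Genes of B-cell development moved in both directions. The recombinase genes Rag1 and Rag2, which cut immunoglobulin gene segments, fell, with differences of -0.89 (SE 0.114) and -1.35 (SE 0.0773), whereas Dntt, the terminal transferase that adds nucleotides at the joints, rose by 1.33 (SE 0.0914). Il7r, the interleukin 7 receptor that pre-B cells need to grow, fell by 0.93 (SE 0.0453). Cd74, the invariant chain of MHC class II, rose by 1.52, while Cd55, a complement regulator, fell by 2.13 and Cd2, a lymphocyte adhesion molecule, fell by 0.62. Among 19 early B-lineage transcription factors Lef1, Foxo1 and Erg fell, with differences of -0.49, -0.51 and -0.33, while Runx1 rose by 0.25.

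That factor list was lower as a group (median -0.09; 1 rose and 3 fell, 3 and 5 adjusted over the list alone; camera adjusted p = 0.0348). With an estimated correlation its adjusted p = 0.779, and its call ended without ERT2 replicate 1 (adjusted p = 0.0515), Cre-ERT2 replicate 1 (0.0827) or Cre-ERT2 replicate 3 (0.0683). Erg lost its call without Cre-ERT2 replicate 3 (0.0516), and Runx1 without any array other than ERT2 replicate 2 (0.0743 to 0.139). The other B-lineage lists did not pass camera, although fry called the progenitor genes lower and the plasma-cell markers higher (adjusted p = 0.00867 each). In V(D)J recombination 2 of 11 rose and 3 fell (4 and 3 adjusted over the list alone, adjusted p = 0.905), and in later B-cell stage genes 2 of 14 rose and 3 fell (2 and 3 adjusted over the list alone, adjusted p = 0.587). Among progenitor genes 2 of 13 rose and 3 fell, Sox4 among them (2 and 3 adjusted over the list alone, adjusted p = 0.118). In the pre-B cell receptor list 2 of 16 rose and 2 fell (2 and 3 adjusted over the list alone, adjusted p = 0.253). Vpreb2, a surrogate light chain gene, rose by 0.49, Plcg2, a phospholipase below the receptor, rose by 0.38, and Cd22, an inhibitory co-receptor, fell by 0.41. Of plasma-cell markers 3 of 7 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.169), with Jchain and Xbp1 (0.38) higher and Sdc1, the syndecan of plasma cells, lower (-0.62). Gfra2 and Flt3, the risen progenitor genes, lost their calls without any 1 of the 6 arrays (0.0516 to 0.152), which left 0 risen. Flt3 also lost it under median centring (0.0528) and cyclic loess (0.0513). In the pre-B cell receptor list 1 fell without any 1 of the 6 arrays. In V(D)J recombination 1 rose without any array other than ERT2 replicate 2, and in later B-cell stage genes 1 rose without ERT2 replicate 1, Cre-ERT2 replicate 2 or Cre-ERT2 replicate 3. Of plasma-cell markers 2 rose without any array other than ERT2 replicate 1. There Mzb1, a further risen member, lost its call (limma adjusted p from 0.067 to 0.14), as it did under median centring (0.0539).

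Targets of Wnt and beta-catenin signalling were lower as a group, though Ccnd1 was higher. Cd44, a hyaluronan receptor, fell by 1.84 (SE 0.0761), Nkd2, a feedback inhibitor of Wnt signalling, fell by 1.06 (SE 0.0738), and Lef1, a nuclear partner of beta-catenin, fell by 0.49 (SE 0.0498). The receptors Lgr5 and Tnfrsf19 and the ubiquitin ligase Rnf43, named after their values were seen, fell, with differences of -0.63, -0.40 and -0.52. Ccnd1, which encodes cyclin D1, rose by 1.53 (SE 0.0536). In all, 1 of 14 rose and 6 fell (1 and 7 adjusted over the list alone; median -0.18; camera adjusted p = 0.00148). With an estimated correlation its adjusted p = 0.779. Tnfrsf19 lost its call without ERT2 replicate 1 or any 1 of the Cre-ERT2 replicates (0.0681 to 0.104).

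TGF-beta targets were not called as a group, with 3 of 15 higher and 5 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.531). The type I receptor Tgfbr1 fell by 1.16 (SE 0.0767) and the type II receptor Tgfbr2 rose by 0.54 (SE 0.0535), while the pathway inhibitors Pmepa1 and Bambi rose by 0.76 and 0.46. The number of lower members was 2 without ERT2 replicate 1 or any 1 of the Cre-ERT2 replicates and 3 without ERT2 replicate 2, as Id3, Tgif1 and Skil lost calls (0.0552 to 0.117). In the Sox family Sox4 was the 1 member of 10 that passed (0 rose and 1 fell, the same counts adjusted over the list alone, camera adjusted p = 0.532).

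Genes of sterol synthesis were higher as a group. Cyp51, the lanosterol demethylase, rose by 0.47 (SE 0.0428), and Msmo1, Sqle and Idi1, enzymes of the same pathway, rose by 0.32, 0.33 and 0.27. In all, 4 of 15 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.20; camera adjusted p = 0.000132). With an estimated correlation its adjusted p = 0.779. Msmo1 lost its call without Cre-ERT2 replicate 3 (0.0585), and Sqle and Idi1 without ERT2 replicate 1 or any 1 of the Cre-ERT2 replicates (0.0558 to 0.104).

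In the glycolysis and hypoxia list Aldoc, an aldolase, fell by 2.22 (SE 0.0764), Bnip3, a mitophagy gene, fell by 0.57 and Pfkp, a phosphofructokinase, fell by 0.55, while Egln3 rose by 2.10. There 2 of 20 rose and 3 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.591), and 1 rose without Cre-ERT2 replicate 1 or Cre-ERT2 replicate 3.

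The DNA replication, Myc target and ATF4 lists were higher with small medians, while the G2-M and culture stress lists were not called. Over all genes 873 of 19938 rose, and the shares of risen DNA replication and Myc target genes lay near that. Of DNA replication genes 1 of 27 rose, Tyms, the thymidylate synthase, by 0.41 (SE 0.0486), and 0 fell (1 and 0 adjusted over the list alone; median 0.10; camera adjusted p = 0.0348). With an estimated correlation its adjusted p = 0.779, and fry did not call it (adjusted p = 0.0829). Of Myc targets and ribosome biogenesis genes 1 of 21 rose, the nucleolar gene Nolc1, by 0.43 (SE 0.0457), and 0 fell (2 and 0 adjusted over the list alone; median 0.10; camera adjusted p = 0.0348). Its adjusted p was 0.779 with an estimated correlation. Of ATF4 and unfolded protein response genes 3 of 19 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.13; camera adjusted p = 0.0413), with Xbp1, a transcription factor of the secretory pathway, up by 0.38 (SE 0.0511), Sesn2 by 0.50 and Herpud1 by 0.24. With an estimated correlation that list too had adjusted p = 0.779. None of 24 G2-M genes passed (0 rose and 0 fell, the same counts adjusted over the list alone, camera adjusted p = 0.253).

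Leaving out single arrays ended these calls. DNA replication lost its call without ERT2 replicate 3 (adjusted p = 0.134), Cre-ERT2 replicate 2 (0.108) or Cre-ERT2 replicate 3 (0.0739), and Myc targets without ERT2 replicate 1 (0.0585), Cre-ERT2 replicate 2 (0.104) or Cre-ERT2 replicate 3 (0.0739). The ATF4 list lost its call without ERT2 replicate 3 (0.102), Cre-ERT2 replicate 2 (0.108) or Cre-ERT2 replicate 3 (0.0847), Sesn2 without ERT2 replicate 3, Cre-ERT2 replicate 1 or Cre-ERT2 replicate 2 (0.0506 to 0.0695), and Herpud1 without any 1 of the 6 arrays (0.064 to 0.193). Herpud1 also lost it under robust fitting (0.0508), median centring (0.0747), a further quantile normalization (0.068) and cyclic loess (0.0616), and without a pseudocount (0.0504). Without ERT2 replicate 2 the number of risen Myc targets was 2. Among the brighter probe sets alone the adjusted p of these lists was 0.105.

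Targets of p53 were higher as a group, although 4 fell. Zmat3, a zinc-finger RNA-binding protein, rose by 0.94 (SE 0.0617), Phlda3, an inhibitor of AKT, by 1.04 (SE 0.0888) and Trp53inp1, a stress-response gene, by 0.50 (SE 0.0485). The other risen members, named after their values were seen, were Plk2 (0.86), Tnfrsf10b (0.56), Sesn2 (0.50), Ddit4 (0.41), Ccng1 (0.40) and Ei24 (0.26). Eda2r, a receptor of the TNF family, fell by 1.19 (SE 0.0995), and Btg2, Plk3 and Rrm2b, also named after their values were seen, fell, with differences of -0.63, -0.83 and -0.30. In all, 9 of 28 rose and 4 fell (14 and 5 adjusted over the list alone; median 0.15; camera adjusted p = 0.0357). With an estimated correlation its adjusted p = 0.779, and its call ended without ERT2 replicate 3 (0.0612), Cre-ERT2 replicate 2 (0.104) or Cre-ERT2 replicate 3 (0.0683) and among the brighter probe sets alone (0.105). Rrm2b lost its call without any 1 of the 6 arrays (0.0565 to 0.121), Ddit4 without any array other than ERT2 replicate 1 (0.0643 to 0.119), Ei24 without any other than ERT2 replicate 2 (0.0671 to 0.107), and Sesn2 without ERT2 replicate 3, Cre-ERT2 replicate 1 or Cre-ERT2 replicate 2 (0.0506 to 0.0695). Cdkn1a and Bax were not analysed here.

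Genes of survival and kinase pathways changed in both directions. Bcl2l1, which encodes the survival protein BCL-XL, fell by 0.79 (SE 0.0554), and Bcl2l2, which encodes BCL-W, rose by 0.46 (SE 0.0543). Bok, a pro-death relative, fell by 0.70 (SE 0.0819). Mtor, the growth-controlling kinase, fell by 1.12 (SE 0.0673), Pik3r3, a regulatory subunit of PI3K, fell by 0.80 (SE 0.08) and Foxo1 fell by 0.51. Dusp4 and Dusp5, phosphatases that switch off ERK and other MAP kinases, rose by 0.98 and 0.44. Pim2, a survival kinase gene induced by STAT5, rose by 0.43, and Zap70, a kinase of antigen receptor signalling, fell by 0.46.

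None of the lists of these pathways passed camera as a group. Of pro-survival genes 2 of 5 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.618), and of pro-death genes 0 of 10 rose and 1 fell (4 and 1 adjusted over the list alone, 0.584). PI3K-AKT components had 1 of 24 higher and 5 lower (3 and 5 adjusted over the list alone, 0.243), and ERK-MAPK genes had 2 of 18 higher and 1 lower (3 and 3 adjusted over the list alone, 0.591). STAT5 targets had 2 of 13 higher and 2 lower (5 and 4 adjusted over the list alone, 0.905), and Src-family and related kinases had 1 of 13 higher and 1 lower (2 and 1 adjusted over the list alone, 0.414). Zap70 lost its call without Cre-ERT2 replicate 1 (0.0512) or Cre-ERT2 replicate 2 (0.0531), and Ptk2b, the risen kinase of that list, without any 1 of the 6 arrays (0.072 to 0.141) and under median centring (0.0539). Among PI3K-AKT components 3 were lower without any array other than ERT2 replicate 3, as Pik3ap1 and Pik3r2 lost calls (0.0561 to 0.149), and 0 were higher without Cre-ERT2 replicate 2 or Cre-ERT2 replicate 3, where Foxo3 lost its call (0.0515 to 0.0542). Of pro-survival genes 1 rose without any array other than ERT2 replicate 2, and of STAT5 targets 1 fell without any array other than ERT2 replicate 3. No ERK-MAPK gene fell without ERT2 replicate 1, ERT2 replicate 2, Cre-ERT2 replicate 1 or Cre-ERT2 replicate 3.

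Markers of other cell types and of culture stress were not called as groups by camera, although fry called the myeloid markers lower (adjusted p = 0.0356). Among T-cell markers Lat and Cd5, a signalling adaptor and a receptor regulator, rose by 0.47 and 0.56, and 0 of 13 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.591). Among myeloid markers Lyz2, which encodes lysozyme, rose by 1.40, and Cybb, the NADPH oxidase subunit, fell by 1.28, with 1 of 17 higher and 2 lower (1 and 2 adjusted over the list alone, 0.584). No NK-cell marker of 10 and no erythroid or megakaryocyte marker of 9 passed (0 rose and 0 fell, the same counts adjusted over the list alone, 0.618 and 0.637). Of stromal markers 0 of 14 rose and 1 fell (0 and 1 adjusted over the list alone, 0.353). The number of fallen myeloid markers was 1 without ERT2 replicate 1 or Cre-ERT2 replicate 2, and no stromal marker fell without any array other than Cre-ERT2 replicate 1.

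Of interferon-stimulated genes 3 of 24 rose and 0 fell (5 and 0 adjusted over the list alone, 0.414), among them Trim30a and Usp18, regulators of innate signalling, by 0.46 and 0.51. NF-kB targets had 0 of 16 higher and 1 lower (2 and 2 adjusted over the list alone, 0.854), and heat shock and culture stress genes 0 of 14 higher and 1 lower (2 and 1 adjusted over the list alone, 0.253). Of histone genes 0 of 8 rose and 1 fell (1 and 2 adjusted over the list alone, 0.169), the linker histone gene H1f2 (-0.55), and fry called this list lower (adjusted p = 0.0455). No NF-kB target was lower without ERT2 replicate 1, Cre-ERT2 replicate 2 or Cre-ERT2 replicate 3, and 2 were without ERT2 replicate 3. No culture stress gene was lower without ERT2 replicate 1, ERT2 replicate 2, Cre-ERT2 replicate 1 or Cre-ERT2 replicate 3. The number of risen interferon-stimulated genes was 2 without any array other than ERT2 replicate 2. Xaf1, a further risen member, lost its call without any 1 of the 6 arrays (limma adjusted p from 0.0658 to 0.154) and under median centring (0.0551).

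Of the 31 lists 7 passed camera with its preset correlation, and none passed with an estimated correlation, where 1 list, the Wnt targets, had an unadjusted p under 0.05 (p = 0.0348). Fry, which asks whether a list's genes move one way and does not compare them with other genes, called 10 lists, and its mixed test, for change in either direction, called 28. In V(D)J recombination, later B-cell stage genes, the Sox family, glycolysis and hypoxia and NK-cell markers the median was above 0 while the mean and camera's direction were below. In ERK-MAPK genes the mean was above 0 and the median and camera's direction below, and in NF-kB targets the median and mean were above 0 and camera's direction below.

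**Figure D3:**
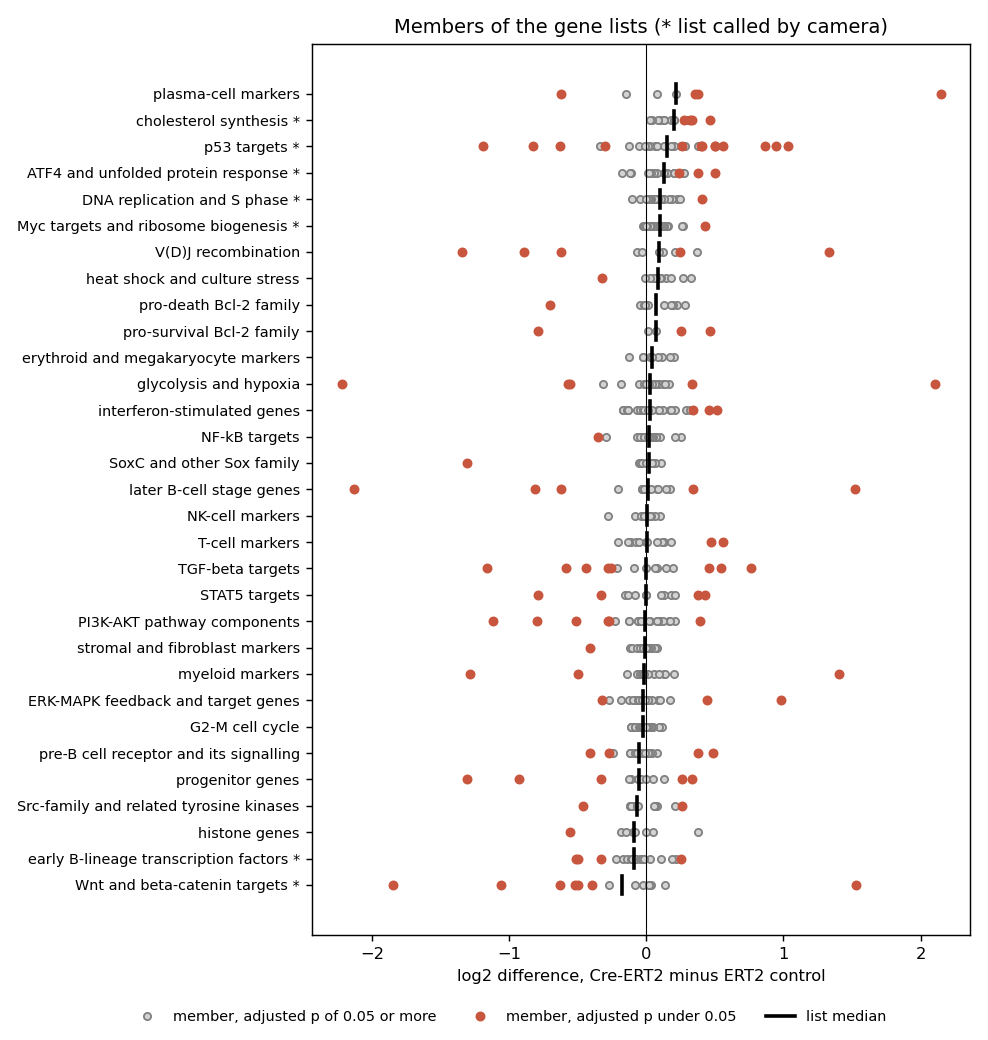
Log2 difference, Cre-ERT2 minus ERT2 control (horizontal axis), of each measured member of the 31 gene lists, 1 row per list, with red points for members past adjusted p 0.05 and a bar at the list median. The medians run from -0.18 in the Wnt targets to 0.22 in the plasma-cell markers, and single members reach -2.22 (Aldoc) and 2.15 (Jchain).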

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

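Tests without a pseudocount and on named probe sets alone were added after seeing the data. The fall of Sox4 kept its call in every alternative run, with differences from -1.42 to -1.25. The 30 genes with the largest changes kept theirs in all 534 combinations of gene and setting that could be run. Some of them were not among the brighter probe sets and were not tested there. Those 30 were picked as the largest changes in the same samples, so their keeping a call was nearly given and is no check. For 149 other genes named or passing in a list or family, 2379 of 2655 combinations kept their side of the threshold, 196, in 38 genes, lost a call, 80 gained one and 0 reversed. Some of those 149 genes had not passed in the main fit, and their staying uncalled counts as kept. The share kept therefore overstates how stable the called genes are. The counts moved most with estimated array weights, to 2415 higher and 1612 lower probe sets, and with a minimum fold of 1.5, which by construction left 393 and 515. With 1 array left out, between 606 and 1319 probe sets were higher, between 654 and 883 lower, and between 2 and 7 lists were called; fewer samples were tested, and at least 57.7% of the original calls were kept. Among the brighter probe sets 3 lists were called, and with an estimated correlation 0 lists; the cause was not tested. Cholesterol synthesis and Wnt targets kept their call in all 15 other settings at the preset correlation that move camera, p53 targets, DNA replication and Myc targets in 11, early B-lineage factors in 12 and the ATF4 list in 10; an intensity trend, robust fitting and named probe sets alone leave camera as it was and are no check of it. Same-numbered samples deviated together with r of 0.20, 0.34 and -0.05, so the numbers were not taken as pairs, and not every sample correlated best with its own number. Samples of different numbers had r from -0.43 to 0.33. With so few samples, a culture or batch shared by number is not excluded. With the replicate number as a block 959 probe sets were higher and 877 lower. In that fit 6 lists were called (ATF4 adjusted p = 0.0552) and Sox4 had adjusted p = 0.00131. Calls of single genes that ended in it are not listed with the genes above. Among them were Herpud1 (limma adjusted p = 0.103), Ptk2b (0.0681), Pik3r2 (0.0565) and Pik3ap1 (0.0553). So were the sterol genes Sqle (0.0552) and Idi1 (0.0648) and the p53 targets Rrm2b (0.0865) and Ei24 (0.0606). Runx1 (0.0649), Gfra2 (0.0562), Mzb1 (0.0549), Tgif1 (0.0626) and Skil (0.0648) lost theirs too. Signal over background limits what can be said of dim probe sets.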

Other observations

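All gene families here were chosen after the values were seen, as were the tests of neighbouring pairs, whole chromosomes, other cell types, the extent of Sox4 loss, Cre damage and Zfp brightness. The 15 families screened by symbol were picked from the same values, so their counts describe these samples and are no test of enrichment. Plexins and semaphorins, guidance receptors and ligands that also act in immune cells, had 7 of 29 higher and 3 lower (34.5% called against 8.06% of other genes). Plxnc1 and Plxnd1 rose by 1.37 and 1.15 and Sema4a by 0.79, while Sema5a fell by 2.26, Plxna2 fell by 2.18 and Plxna3 fell by 1.04. Under cyclic loess 6 members were higher and 3 lower, and 5 were higher without any array other than ERT2 replicate 2. Gimap GTPases, which act in lymphocyte survival, had 5 of 8 higher and 0 lower, with Gimap4 at 2.62, Gimap8 at 0.89 and Gimap6 at 0.53. The number of risen Gimap genes was 3 without ERT2 replicate 1, ERT2 replicate 3 or Cre-ERT2 replicate 1, and under cyclic loess 1 member fell. Nlrp and Ifi genes had 6 of 47 higher and 4 lower, with 3 higher without ERT2 replicate 1, Cre-ERT2 replicate 2 or Cre-ERT2 replicate 3. Sialyl-, N-acetylglucosaminyl- and N-acetylgalactosaminyltransferases had 4 of 48 higher and 5 lower, with 2 higher without ERT2 replicate 3 or any 1 of the Cre-ERT2 replicates. Of Fc receptor-like genes Fcrl6 and Fcrla rose by 2.47 and 1.53, and 0 of the other 4 were called.

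Among genes changed more than 2-fold, 7 neighbouring pairs moved in the same direction and 2 in opposite directions, against a median of 2 same-direction pairs in 10000 shuffles over the gene order (permutation p = 0.0034). The pairs were Gpr171 and P2ry14, Zkscan16 and Ptgr1, Zfp980 and Zfp600, Ptpn12 and Gsap, Cyp4f18 and Olfr372, Olfr372 and Olfr373, and Tceal9 and Bex3. The shuffles take neighbours as measured independently, and Olfr372 was counted with each of its neighbours. Signal shared between adjacent genes or paralogs, such as Olfr372 and Olfr373 or Zfp980 and Zfp600, was not tested. The permutation p is therefore no evidence that neighbouring genes were regulated together. The median differences of the 20 chromosomes with 100 or more genes lay between 0.01 and 0.03.

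The number of called probe sets was 2152 in the real grouping, which 1 of the 10 splits of the 6 samples reached, and the highest of the other splits gave 0. So few splits cannot give a share under 0.05. Every other split mixed the groups, so any difference between the groups entered its spread. A low count there was nearly given and is no check of the called probe sets.

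Many genes fell far more than Sox4. T-cell, NK-cell, myeloid, erythroid or stromal cells would bring all their abundant transcripts, and as the cause of changes over 4-fold they are argued against by list medians of at most 0.0404 and by 0 of 63 markers changing that far. Smaller shares of such cells are not excluded: the lists are dim (median log2 levels 6.38 to 7.92), and although Col1a1 and S100a9 had differences of 0.06 and 0.09, Cd5 rose by 0.56, Lyz2 rose by 1.40, Cybb fell by 1.28 and fry called the myeloid markers lower (adjusted p = 0.0356). Plasma-cell markers were left out of this test, so it does not speak to plasma cells. Of those markers 3 of 7 rose, Jchain by 2.15, and 1 fell. Their median was 0.22, and fry called them higher (adjusted p = 0.00867) while camera did not (adjusted p = 0.169). If the 40.3% of Sox4 signal that remained came from cells that kept the gene, and other genes fell only where Sox4 was lost, none could fall further than Sox4, yet 96 probe sets did so by over 2 standard errors. Background signal in the Sox4 probe set, or Sox4 RNA outlasting the deletion, may account for this and was not tested, and a difference in clones between the cultures of the groups stays open, as does an effect of Sox4 loss.

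The rise of p53 targets, called by camera at its preset correlation but not with an estimated one (adjusted p = 0.779), may reflect DNA damage from Cre recombinase and not loss of Sox4. Such damage was set to need a list median over 0.5, and loss of Sox4 alone a median of 0 or below. These bounds were set after the values were seen, and no measurement here backs them. The median was 0.15, between those bounds, which decides nothing. Since every Cre-ERT2 sample also carried floxed Sox4, the explanations cannot be told apart. Well-known targets went both ways, with Zmat3, Plk2, Tnfrsf10b and Ccng1 at 0.94, 0.86, 0.56 and 0.40 and Eda2r at -1.19, while Mdm2, Pmaip1, Fas and Sesn1 did not pass (0.03, 0.02, -0.05 and 0.06).

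Of 317 Zfp genes 28 rose (8.83% against 4.31% of other genes) and 15 fell. Fisher's exact test of the risen genes gave p = 0.000433 and camera p = 0.429 (p = 0.82 with an estimated correlation), and since the family was picked from the same values neither is independent evidence. Brightness may account for part of this: 10000 gene sets of like expression had a median of 20 risen genes and a 99th percentile of 31. The observed 28 lies at percentile 94.3 of those sets. A first version on the family median, replaced after its result was seen because only some members rose, gave percentile 71.7. Signal shared between neighbouring paralogs stays open, since 32.1% of the risen Zfp genes had a risen Zfp neighbour. Under cyclic loess 28 rose and 26 fell, and without single arrays between 15 and 33 rose and between 6 and 11 fell; no biological explanation was tested.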
